A study of Mus musculus with 6 samples.

How the data were processed

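Ribosomal-RNA-depleted total RNA from the forebrain of 6 mouse embryos at embryonic day 15.5 was sequenced, with single-end reads and a strand-marking library kit, per the labels' protocols. The genotype field of the labels assigned 3 libraries to Arx wt/0 and 3 to Arx dup24/0, and replicates were numbered in the order of deposition. The sample titles carry the word ko on the libraries whose genotype field reads wt/0, and the word wt on those whose genotype field reads dup24/0. The genotype field was followed, because the source field repeats it. Groups are therefore named by label throughout, and if the titles are right instead, every direction reverses. The titles give 1 library labelled dup24/0 the number 179 and the other 5 libraries the number 178, read here as a litter number. Nothing in the labels says more about how the embryos were chosen.

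The deposited table holds 35477 RefSeq transcript rows on the mm9 build. Reads were aligned with GSNAP and scaled with DESeq2 by the authors, per the submitters' processing notes and the file headers, and versions are not given in the sources used here. Per the file headers, the signal of each transcript in each library is the number of bases sequenced over it after the authors' scaling, that is, coverage and not a count of reads. All values (100.0%) were whole multiples of 1 step per library within a tolerance of 0.01, which gave back the unscaled bases. Low values piled up at multiples of 42 bases, and 42 bases was taken as the read length, an inference from the values. The authors' deposited table also holds a p-value and a score (a normal quantile with a sign) for each row. In all 638 rows with the authors' p-value under 0.05, the score is positive where the libraries labelled wt/0, which are titled ko, are higher. This sign was not used to choose between the conflicting labels.

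The design fixed before the data were examined called for a count test, with limma on log2 values as its fallback. Because the values count bases and not reads, the planned edgeR test was not run and the planned DESeq2 alternative was not run. The main test was limma 3.58.1 in R 4.3.3 on log2(value + 1) with a mean-variance trend, on the deposited scaling, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on that log2 scale. The added 1 shrinks them little, since the genes kept had a mean of at least 420 scaled bases. Single libraries with very low values can weigh heavily on a difference. Each of the 24507 gene symbols was represented by its transcript with the highest mean over the 6 libraries, and 5785 genes had more than 1 transcript row. Of 1413 rows named by accession alone, 1406 were given a symbol from a RefSeq table of the GRCm38.p6 assembly, which was used for names and gene order and for no coordinates. Genes with a mean under 420 scaled bases (10 reads) were left out, which kept 15773 genes. A group of 1308 genes shared all 6 values with another gene, and such genes cannot be told apart in this table.

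The 28 gene lists were fixed before the data were examined. Of these, 26 were tested with limma's camera at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. No gene of the mitochondrial list was among the genes tested, and the sex-linked list was read per library. Named genes were Arx and its neighbour Pola1, the 4 genes with the smallest p in each direction where fewer than 4 passed the threshold, and the 2 members with the smallest p in each list without a member past it. A list score is the median over the list's members of log2(value + 1) minus each gene's mean over the 6 libraries. Comparisons of 3 against 3 scores used a two-sided exact permutation test, whose smallest possible p is 0.1.

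The fit was tested on simulated data for this comparison, in 10 simulations over 15773 genes. It recovered 48.2% of genes changed 1.5-fold, 76.2% of those changed 2-fold, 87.8% at 3-fold and 92.0% at 4-fold, and 7.6% of calls were false. The list test called 10 of 10 lists of 16 genes shifted by 0.3 on the log2 scale and 0 of 250 unshifted lists. Those simulated genes varied independently of each other, which real lists do not. The simulated libraries also held no differences by title style, title number, sex or tissue. Each simulation planted many changed genes, which eases the adjusted threshold. The rates of recovery need not hold for the real libraries, and an absence of calls there does not exclude changes of these sizes.

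Alternatives covered scaling (trimmed mean, library size alone, abundant genes removed first), limma-voom on bases divided by the read length, 2 other filters, title style as a term, 2 other thresholds and each library left out in turn. Settings chosen after seeing the data were a pseudocount of 1 read, no variance trend, the median transcript, library weights, the thalamus score as a term, an estimated correlation in each setting, and leaving out both the library with female expression and the library numbered 179. The median log2 difference of all genes ran from -0.0026 to 0.0022 over the deposited and alternative scalings. Plots and tables used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.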

Results

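The series measured RNA in the forebrain of 6 mouse embryos at embryonic stage E15.5, with 3 libraries labelled Arx wt/0 and 3 labelled Arx dup24/0. Arx is an X-linked homeobox gene that acts in the development of cortical interneurons, and the series title describes dup24 as a mouse model of a human ARX mutation. Coverage summed over genes was 1029877407, 857028071 and 788727180 bases in the libraries labelled wt/0. It was 644153971, 724298631 and 743145747 bases in those labelled dup24/0. At the inferred read length these are 15336999 to 24520891 reads per library. The 10 genes with the most bases took 5.72% to 6.31% of each library. The labels name embryos but not how they were sampled, so the p-values measure the spread between these libraries.

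Arx was measured first. Its values were 59979, 33601 and 43495 scaled bases in the libraries labelled wt/0 and 52935, 75694 and 44234 in those labelled dup24/0. The means were 45692 ± 13326 and 57621 ± 16245 (SD, n = 3 each), and the log2 difference of 0.34 ± 0.24 (SE) had an adjusted p of 0.9997 in limma. The groups overlapped. A duplication within the gene need not alter its level, so Arx cannot tell which of the conflicting labels is right. Its neighbour Pola1, a DNA polymerase subunit gene, had means of 49218 ± 9447 and 45559 ± 1636 scaled bases (SD, n = 3 each), with a log2 difference of -0.09 ± 0.13 (SE).

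Sex-linked genes set 1 library apart. Both genotype labels describe embryos with a single Arx allele, the state of males. In the library labelled wt/0 replicate 3, Xist, the RNA that silences an X chromosome in females, was at 1687802 scaled bases, against 715 to 8840 in the other 5. Its antisense partner Tsix was at 167738 there. In the same library the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty were at 38.6, 83.1, 4.9 and 83.1 scaled bases. The lowest values elsewhere were 59713 for Ddx3y, 74909 for Kdm5d, 30053 for Eif2s3y and 53682 for Uty.

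**Figure D1:**
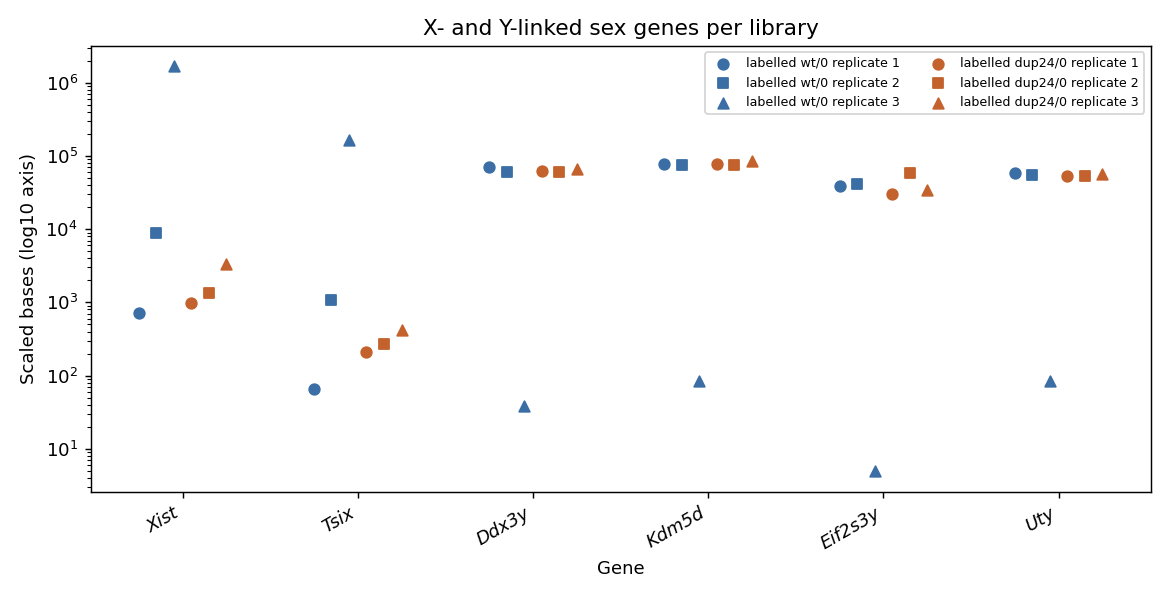
Scaled bases (log10 axis) of Xist, Tsix and 4 Y-linked genes, with 1 point per library, coloured by labelled group. The library labelled wt/0 replicate 3 has Xist at 1687802 and each of the Y-linked genes under 100 scaled bases.

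No gene passed the threshold between the libraries labelled dup24/0 and those labelled wt/0. Limma called 0 of 15773 genes at an adjusted p of 0.05 and 0 at 0.10, with a smallest adjusted p of 0.9997, and limma-voom called 0. At an unadjusted p under 0.05 there were 509 genes, where chance would give 789. The 2 groups did not overlap in 1306 genes, or 8.28%, and chance gives 10% for 3 against 3. Without the library labelled dup24/0 replicate 1, 1 gene passed, Atp9a, and without both that library and the one with female expression the count was also 1. The authors' deposited table, whose p-values come from the authors' own model, holds 638 of 35477 rows with p under 0.05. After Benjamini-Hochberg adjustment of those p-values over the 31012 rows above 0, 15 rows of 8 genes in the authors' deposited table lay under 0.05: Ikzf1, Rxrg, Rnd2, Gli3, Sall1, Tac1, Emx1 and Neurog2. Adjusted over all 35477 rows, 12 rows lay under 0.05, which leaves out Emx1 and Neurog2 (adjusted p = 0.0512 each).

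The genes with the smallest p are named here as not past the threshold (adjusted p 0.9997 in limma for each). Rnd2, a Rho-family GTPase of migrating cortical neurons, had means of 31155 ± 1016 scaled bases in the libraries labelled wt/0 and 21580 ± 1080 in those labelled dup24/0 (SD, n = 3 each). Its log2 difference was -0.53 ± 0.08 (SE). Gli3, a transcription factor of Hedgehog signalling and dorsal forebrain patterning, differed by -0.46 ± 0.08, Sall1, a zinc-finger transcription factor, by -0.55 ± 0.10, and Hk2, a hexokinase, by -0.50 ± 0.09. In the other direction, Ikzf1, a zinc-finger transcription factor of striatal neurons, had means of 2712 ± 368 and 7265 ± 2190 scaled bases, a log2 difference of 1.39 ± 0.22. Rxrg, a retinoid X receptor, differed by 1.54 ± 0.29, Tac1, the substance P precursor, by 0.76 ± 0.15, and Hs3st5, a heparan sulfate sulfotransferase, by 0.67 ± 0.12. In each of these 8 genes the 3 libraries of one group lay above the 3 of the other.

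**Figure D2:**
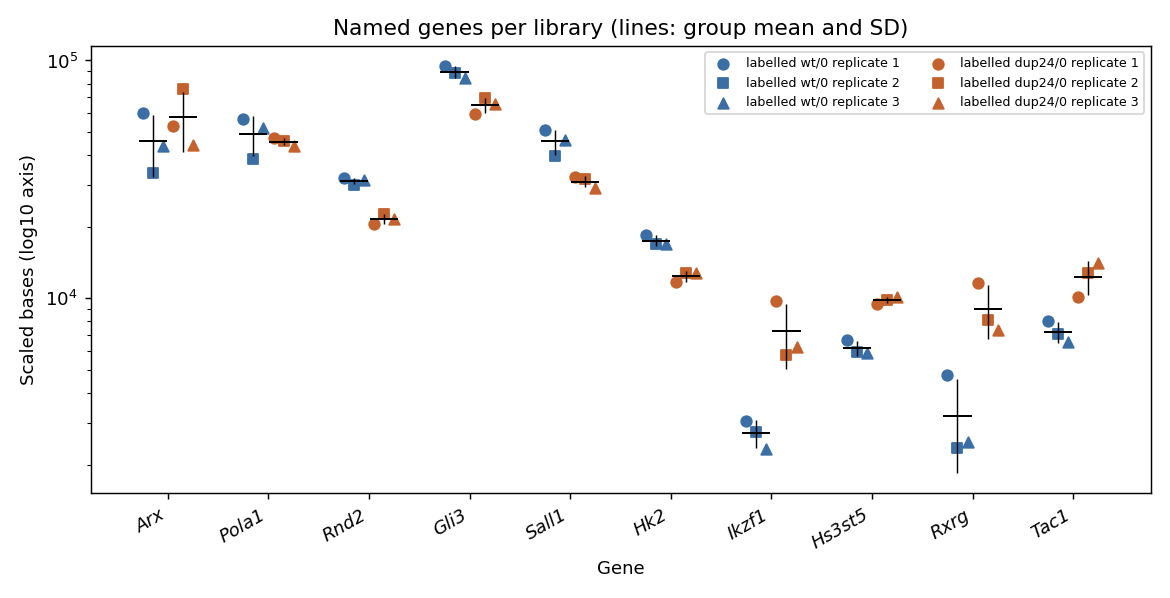
Scaled bases (log10 axis) of Arx, Pola1 and the 8 genes with the smallest p, with 1 point per library, and lines for the mean and SD of each labelled group. The groups overlap for Arx and Pola1 and do not overlap for the other 8, none of which passed the adjusted threshold.

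At the level of gene lists, camera with the preset correlation called 9 of 26 lists, 0 of which held with an estimated correlation or with fry. The genes of striatal projection neurons had higher values in the libraries labelled dup24/0 in 19 of 19 members, with a median log2 difference of 0.39 (adjusted p = 2.02e-11 with the preset correlation, and adjusted p = 0.373 with an estimated correlation). Their 2 members with the smallest p were Ikzf1 and Rxrg. Adjusted over all genes 0 members passed, and adjusted over the list alone 4 did. The list score was -0.17 ± 0.34 in the libraries labelled wt/0 and 0.17 ± 0.16 in those labelled dup24/0 (SD, n = 3 each), and the exact permutation p was 0.3.

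Lists of dividing and pallial progenitor cells had lower values in the libraries labelled dup24/0. Of 16 genes of cortical radial glia, the stem cells of the cortex, 14 were lower, with a median of -0.21 (adjusted p = 5.31e-09 with the preset correlation, adjusted p = 0.373 with an estimated correlation). The groups did not overlap in 8 of them, and adjusted over the list alone 6 passed. The homeobox genes Emx1 and Emx2 differed by -0.59 ± 0.12 and -0.50 ± 0.13 (SE). Without dup24/0 replicate 2 the median was -0.38. Without both the library with female expression and dup24/0 replicate 1, the radial glia list was no longer called (median -0.14, adjusted p = 0.103). Of 12 genes of intermediate progenitors, 10 were lower, with a median of -0.31 (adjusted p = 3.97e-08 preset, adjusted p = 0.111 with an estimated correlation), and adjusted over the list alone 2 passed. Neurog2 and Eomes, transcription factors of excitatory neurogenesis, differed by -0.48 ± 0.09 and -0.56 ± 0.13. All 20 of 20 cell cycle genes were lower, with a median of -0.24 (adjusted p = 2.03e-11 preset, adjusted p = 0.537 with an estimated correlation, which was 0.823), and adjusted over the list alone 0 passed. The groups overlapped in each of these genes, and the exact permutation p of the list score was 0.2. Without wt/0 replicate 1 the cell cycle median was -0.13. Mcm3 and Mcm2, subunits of the replicative helicase, differed by -0.33 ± 0.12 and -0.28 ± 0.11.

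**Figure D3:**
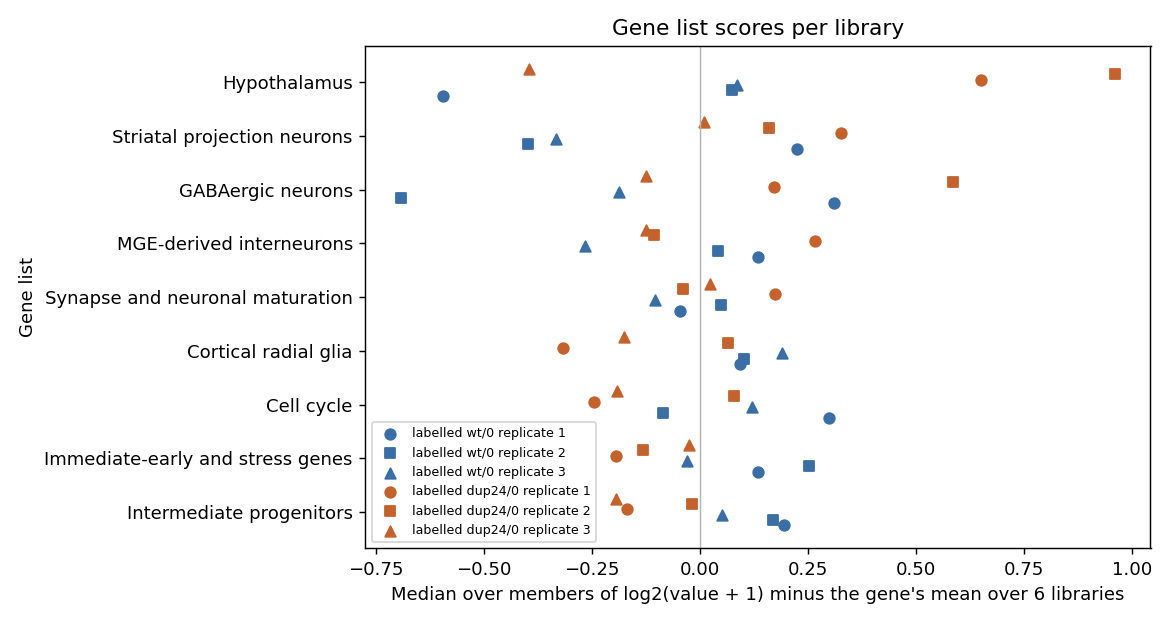
Scores of the 9 lists called by camera with the preset correlation, with 1 point per library. The horizontal axis is the median over the list's members of log2(value + 1) minus the gene's mean over the 6 libraries. Of these lists, the groups do not overlap for intermediate progenitors and cortical radial glia. The exact permutation p was 0.1 for each of these, the smallest possible, and at least 0.2 for the other lists shown. By chance the groups of a list do not overlap in 10% of cases, and 26 lists were tested.

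The GABAergic and medial ganglionic eminence lists had more genes at higher than at lower values in the libraries labelled dup24/0, and single libraries ended both calls. Of 16 GABAergic genes, 14 were higher, with a median of 0.36 (adjusted p = 7.44e-05 preset, adjusted p = 0.537 with an estimated correlation), and without the library labelled wt/0 replicate 2 the list was not called (median 0.14, adjusted p = 0.126). Its median was 0.63 without wt/0 replicate 1 and 0.18 without dup24/0 replicate 2. The GABA transporter Slc6a1 and the GABA-synthesising enzyme Gad1 differed by 0.21 ± 0.07 and 0.31 ± 0.14 (SE). The list of interneurons from the medial eminence had 14 of 20 genes higher, with a median of 0.10 (adjusted p = 0.0178 preset, adjusted p = 0.849 with an estimated correlation). It lost its call without wt/0 replicate 3 (median 0.0010, adjusted p = 0.846) and without dup24/0 replicate 1 (adjusted p = 0.984, median -0.01), and its leading members were Tac1 and Npy, a neuropeptide that differed by 0.88 ± 0.23. Without both of those libraries its median was -0.20 (adjusted p = 0.0178), and with the thalamus score as a term it was 0.01 (adjusted p = 0.706). Leaving out wt/0 replicate 1 or dup24/0 replicate 3 gave medians of 0.16 and 0.18. Adjusted over the list alone 0 GABAergic genes and 2 genes of the medial eminence list passed.

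Another 3 lists were called with the preset correlation. Hypothalamic genes were higher in 16 of 17 (median 0.60, adjusted p = 0.000651 preset, adjusted p = 0.537 with an estimated correlation), and the list lost its call without wt/0 replicate 1 (median 0.29, adjusted p = 0.133) and without dup24/0 replicate 2 (median 0.29, adjusted p = 0.0602). Its median was 0.27 without dup24/0 replicate 1, 1.13 without dup24/0 replicate 3 and 0.34 with the thalamus score as a term. Otp and Avp differed by 1.44 ± 0.53 and 1.30 ± 0.50 (SE). Both had low values, near the filter of 420 scaled bases in the libraries labelled wt/0. The means in the libraries labelled wt/0 and dup24/0 were 543 and 1620 for Otp, and 485 and 1074 for Avp. Synaptic genes were higher in 15 of 20 (median 0.06, adjusted p = 0.0435 preset, adjusted p = 0.561 with an estimated correlation), and the call was lost without wt/0 replicate 1 (median 0.050, adjusted p = 0.203), without wt/0 replicate 3 (median 0.031, adjusted p = 0.549), without dup24/0 replicate 1 (median -0.012, adjusted p = 0.277) and without dup24/0 replicate 3 (median 0.094, adjusted p = 0.0527). The median was highest without wt/0 replicate 2, at 0.13. The call was also lost with title style as a term (adjusted p = 0.0798), with limma-voom, with no variance trend (adjusted p = 0.103), with the thalamus score as a term (adjusted p = 0.143) and without both wt/0 replicate 3 and dup24/0 replicate 1 (adjusted p = 0.916). The median stayed at 0.056 with title style as a term and with no variance trend, and was 0.0070 with the thalamus term and 0.031 without both libraries. Stmn2 and Nefm differed by 0.23 ± 0.09 and 0.30 ± 0.16. Immediate-early and stress genes, which can respond to tissue handling, were lower in 9 of 14 (median -0.27, adjusted p = 0.0178 preset, adjusted p = 0.373 with an estimated correlation). That call was lost without wt/0 replicate 2 (median -0.054, adjusted p = 0.0681), dup24/0 replicate 1 (median -0.13, adjusted p = 0.0921) or dup24/0 replicate 2 (median -0.21, adjusted p = 0.0596). It was lost too without both wt/0 replicate 3 and dup24/0 replicate 1 (median -0.30, adjusted p = 0.0573) and with the thalamus score as a term (median -0.21, adjusted p = 0.0725). Fos and Ier2 differed by -0.92 ± 0.30 and -0.60 ± 0.19. Adjusted over the list alone 0 genes passed in each of these 3 lists.

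The lists closest to the study's subject were not called with all 6 libraries. Arx-responsive genes had a median of -0.08 and a mean of 0.02, which differ in sign (12 genes, adjusted p = 0.584), with Kdm5c at -0.15 ± 0.10 (SE) and Gbx1 at 0.85 ± 0.61. Kdm5c was highest in the library with female expression, at 251673 scaled bases against 186599 to 197942 elsewhere. With 1 library left out Kdm5c ran from -0.23 to -0.029, and the smallest difference came without the library with female expression. Gbx1 ran from 0.13 to 1.44. Its values were low, with means of 677 scaled bases in the libraries labelled wt/0 and 971 in those labelled dup24/0. Neighbours of Arx had a median of -0.03, while the test leaned to higher values (8 genes, adjusted p = 0.966), with Pcyt1b at 0.20 ± 0.11 and Klhl15 at -0.11 ± 0.14. Migration and guidance genes had a median of 0.05 (26 genes, adjusted p = 0.966), with the netrin receptor Dcc at -0.35 ± 0.08 and Nrp2 at -0.28 ± 0.12. Epilepsy and intellectual disability genes had a median of 0.01 (27 genes, adjusted p = 0.141), with Slc6a1 as above and the GABA receptor subunit Gabrb3 at 0.16 ± 0.08. The epilepsy list was called without wt/0 replicate 2 (median 0.080, adjusted p = 0.0275) and without dup24/0 replicate 2 (median 0.074, adjusted p = 0.00285), in both at the preset correlation alone. Adjusted over the list alone 0 genes passed in each of these 4 lists.

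Among other forebrain lists, interneurons from the caudal ganglionic eminence had a median of -0.07 (adjusted p = 0.592), with Egfr at 0.18 ± 0.13 and Adarb2 at 0.17 ± 0.12 (SE). Subpallial progenitors had a median of -0.09 (adjusted p = 0.341), with Lhx2 at -0.49 ± 0.12 and Gsx1 at 0.89 ± 0.57, and adjusted over the list alone 1 gene passed. The ventral cholinergic lineage had a median of 0.06 (adjusted p = 0.636), with Isl1 at 0.92 ± 0.46 and Fgf17 at -1.28 ± 0.70. Values of Gsx1 and Fgf17 were low. The means in the libraries labelled wt/0 and dup24/0 were 773.2 and 1429.5 scaled bases for Gsx1, and 1043 and 441 for Fgf17. Cortical projection neurons had a median of 0.01 (adjusted p = 0.593), with Slc17a7 at -0.40 ± 0.21 and Satb2 at 0.72 ± 0.42. Cajal-Retzius cells had a median of -0.26 (adjusted p = 0.233), with Trp73 at -0.40 ± 0.26 and Ebf2 at -0.28 ± 0.19.

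Several of these lists were called with libraries left out, at the preset correlation alone. With an estimated correlation 0 lists were called in each of these settings. For cortical projection neurons the estimate was 0.57 with all 6 libraries (adjusted p = 0.956). Subpallial progenitors were called lower without wt/0 replicate 2 (median -0.19, adjusted p = 0.0310) and without dup24/0 replicate 2 (median -0.24, adjusted p = 0.00437). Cajal-Retzius genes were called lower without wt/0 replicate 1 (median -0.32, adjusted p = 0.00182) and without dup24/0 replicate 3 (median -0.27, adjusted p = 0.00640). Over the single libraries left out, their median came as near to no difference as -0.083. Cortical projection neurons were called lower without dup24/0 replicate 1 (median -0.20, adjusted p = 0.0243) and without both it and wt/0 replicate 3 (median -0.38, adjusted p = 1.06e-06), and higher without dup24/0 replicate 2 (median 0.16, adjusted p = 0.0449). The cholinergic lineage was called lower without wt/0 replicate 2 (median -0.36, adjusted p = 0.0274) and higher without both wt/0 replicate 3 and dup24/0 replicate 1 (median 0.43, adjusted p = 0.0124).

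Of the lists for other tissues, hypothalamus alone was called with all 6 libraries. The thalamus scores were -0.08, 0.10 and 0.44 in the libraries labelled wt/0 and -1.13, 0.11 and 0.54 in those labelled dup24/0. Between the groups the thalamus list had a median of -0.32 (adjusted p = 0.0541), with Irx3 at -0.77 ± 0.40 and Lef1 at -0.40 ± 0.26 (SE). Eye genes had a median of -0.42 (7 genes, adjusted p = 0.0613), with Mitf at -0.47 ± 0.18 and Pmel at -0.76 ± 0.34. Choroid plexus genes had a median of 0.10 (adjusted p = 0.341), with Aqp1 at 0.55 ± 0.30 and Tmem72 at 0.69 ± 0.51. Blood genes had a median of -0.05 (adjusted p = 0.245), with Gypa at -0.62 ± 0.30 and Hba-x at -0.42 ± 0.29. Hba-x was low in dup24/0 replicate 1, and with 1 library left out its difference ran from -0.65 to -0.028. Endothelial genes had a median of 0.03 (adjusted p = 0.810), with Kcnj8 at 0.30 ± 0.12 and Flt1 at -0.20 ± 0.10. Microglial genes had a median of -0.02, while the test leaned to higher values (adjusted p = 0.974), with P2ry12 at 0.34 ± 0.17 and C1qb at 0.18 ± 0.13. Meningeal genes had a median of -0.05 (adjusted p = 0.341), with Lama1 at -0.24 ± 0.11 and Col1a1 at -0.26 ± 0.25. Oligodendrocyte precursor genes had a median of 0.05 and a mean of -0.01, which differ in sign (adjusted p = 0.810), with Bcas1 at -0.62 ± 0.52 and Gpr17 at 0.41 ± 0.34. With 1 library left out Bcas1 ran from -0.93 to -0.048 and Gpr17 from 0.11 to 0.76.

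The calls of these lists changed with the setting too, again at the preset correlation alone. With an estimated correlation 0 lists were called in each of these settings. With all 6 libraries the estimate was 0.66 for thalamus, 0.77 for meninges and 0.47 for choroid plexus. Thalamus genes were called lower with title style as a term (adjusted p = 0.0307) and without wt/0 replicate 1 (median -0.36, adjusted p = 0.00564), dup24/0 replicate 2 (median -0.56, adjusted p = 0.00960) or dup24/0 replicate 3 (median -0.56, adjusted p = 1.10e-06). Without both wt/0 replicate 3 and dup24/0 replicate 1 they were called higher (median 0.29, adjusted p = 0.000107). Eye genes were called lower with no variance trend (median -0.42, adjusted p = 0.0316), with library weights (median -0.33, adjusted p = 0.0406) and without dup24/0 replicate 2 (median -0.56, adjusted p = 0.00895). Choroid plexus genes were called higher without wt/0 replicate 3 (median 0.30, adjusted p = 0.00669), without dup24/0 replicate 3 (median 0.34, adjusted p = 0.00391) and without both wt/0 replicate 3 and dup24/0 replicate 1 (median 0.35, adjusted p = 0.00871). Blood genes were called lower without wt/0 replicate 1 (median -0.26, adjusted p = 0.000570) and without dup24/0 replicate 2 (median -0.16, adjusted p = 0.0301). Meningeal genes were called lower without wt/0 replicate 1 (median -0.15, adjusted p = 0.0274), without dup24/0 replicate 1 (median -0.24, adjusted p = 0.000263) and without both wt/0 replicate 3 and dup24/0 replicate 1 (median -0.19, adjusted p = 0.0102). They had a median of 0.19 (adjusted p = 0.00389) without dup24/0 replicate 2.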

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

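No paired analysis was possible because the labels give the groups no shared replicate numbers. Depth was 15336999 to 24520891 read equivalents, and it separated the labelled groups. Each library labelled wt/0 had at least 18779219 and each labelled dup24/0 at most 17693946, so depth and labelled group cannot be told apart. Limma called 0 genes under every scaling, filter, threshold and added model, except that 1 gene passed without the female library and dup24/0 replicate 1 (774 genes at an unadjusted p under 0.05, against 509). Leaving out 1 library gave 0 to 1 called genes, 432 to 759 genes at an unadjusted p under 0.05, and 8 to 14 called lists against 9. The highest list count came without dup24/0 replicate 2. It was 6 with the thalamus score as a term, which ended the calls of medial eminence interneurons, synapse and immediate-early genes, and 8 with limma-voom, which ended that of synapse. With title style as a term it stayed at 9, with synapse lost and thalamus gained. The list count was 0 with fry, and 0 with an estimated correlation in every setting that was run with one. Arx stayed higher in the libraries labelled dup24/0, by 0.12 to 0.56 (log2) with 1 library left out. The settings without both of these libraries, with library weights and with the thalamus term were chosen after seeing the data, and the causes of the changes below were not tested.

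With 1 library left out, log2 differences of named genes that changed sign ran from -0.26 to 0.021 for Pola1 and from -0.47 to 0.014 for Col1a1. List medians that changed sign ran from -0.078 to 0.034 for Arx neighbours, -0.014 to 0.18 for medial eminence interneurons, -0.24 to 0.033 for subpallial progenitors, -0.36 to 0.26 for the cholinergic lineage and -0.20 to 0.16 for cortical projection neurons. They also ran from -0.016 to 0.048 for migration, -0.021 to 0.080 for epilepsy genes, -0.012 to 0.13 for synapse, -0.56 to 0.13 for thalamus, -0.066 to 0.34 for choroid plexus and -0.26 to 0.095 for blood. For the remaining lists they ran from -0.028 to 0.080 for endothelium, -0.10 to 0.071 for microglia, -0.24 to 0.19 for meninges, -0.047 to 0.15 for oligodendrocyte precursors and -0.56 to 0.015 for eye.

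Without the female library and dup24/0 replicate 1, signs changed for Satb2 (-0.059), Gpr17 (-0.031), and the medians of Arx-responsive genes (0.0069), medial eminence interneurons (-0.20), subpallial progenitors (0.19), cortical projection neurons (-0.38), Cajal-Retzius cells (0.0040), migration (-0.064), epilepsy genes (-0.034), thalamus (0.29), blood (0.014), endothelium (-0.022) and oligodendrocyte precursors (-0.053). Library quality weights gave -0.0064 for the cholinergic lineage and -0.0018 for cortical projection neurons. The thalamus score as a term gave -0.15 for cortical projection neurons, -0.016 for epilepsy genes and 0.013 for blood. Over the 14 settings in which the medians of the 26 lists were recomputed, limma-voom not among them, 278 kept direction and side of the threshold and 45 changed sign. With the sign kept, 23 passed the threshold and 18 lost it. Calls gained or lost along with a changed sign are counted among the 45.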

Other observations

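The tests of progenitor scores, Y-linked genes, Xist, read-length shares, thalamus scores, steps, title style alone and called lists in other splits were chosen after their results were seen, as was leaving out 2 libraries together. Atp9a, a flippase gene chosen after its values were seen, stood at 32747, 33898 and 32249 scaled bases in the libraries labelled wt/0 and 32420, 135155 and 153985 in those labelled dup24/0. It was the gene that passed without dup24/0 replicate 1 (adjusted p = 0.000175 in limma, against 0.9997 with all libraries), and it also passed without both that library and the one with female expression (adjusted p = 0.00187). Over the leave-one-out settings the smallest adjusted p of any gene was otherwise 0.638 or more. Among 12197 genes with a mean of at least 100 reads, 6 showed a step of more than 0.9 (log2) that exceeded 3 times the remaining range. Of these, 4 were the Y-linked genes, and the others were Atp9a and the embryonic globin Hba-x. Most genes next to Atp9a did not share its step: the mean of both high libraries over the mean of the other 4 was 4.40 for Atp9a, 0.891 for Nfatc2, 0.596 for Sall4 and 1.03 for Zfp64. The exception was Mir7004, with under 200 scaled bases in each library and a ratio of 4.88.

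Embryonic globins were lower in dup24/0 replicate 1, whose title carries another number than the rest, than in the other 5. Hbb-y was at 25347 scaled bases there and at 47438 to 76629 elsewhere, and Hba-x was at 4986 there and at 10668 to 12323 elsewhere. Its adult globin Hba-a1, at 619141, lay within the range of the others.

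The lists of radial glia and intermediate progenitors together (28 genes) had a score difference of -0.27 ± 0.09 (SE) between the groups. These lists were combined after both were seen to be lower, so the score is no independent support. A difference remained without either doubted library: -0.21 ± 0.08 without dup24/0 replicate 1 and -0.26 ± 0.11 without the female library. So few libraries do not settle how much either contributed. Without both, the medians were -0.14 for radial glia (adjusted p = 0.103 in camera, preset correlation) and -0.27 for intermediate progenitors (adjusted p = 0.000107). A smaller pallial share of the dissected tissue may be a cause of the lower progenitor score. If the progenitor genes mark the pallium alone, which was not tested, this predicts that cortical projection neuron genes are lower by as much. Their score exceeded the progenitor score by 0.33 ± 0.33 between the groups, which decides nothing. With single libraries left out, the projection neuron list was called in both directions at the preset correlation: lower without dup24/0 replicate 1 (median -0.20, adjusted p = 0.0243) and higher without dup24/0 replicate 2 (median 0.16, adjusted p = 0.0449). Of the single libraries left out, the latter gave the lowest progenitor medians, at -0.38 and -0.41. With an estimated correlation the list was called in neither. The genotype stays open, as does chance.

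The library labelled wt/0 replicate 3 had female expression. Male RNA mixed into it is excluded by its Y-linked genes, which were at most 0.155% of the lowest other library. A male embryo without its Y chromosome is excluded by Xist, 191 times the highest other library. A female embryo is the candidate explanation that remains, and a test of it written beforehand asked for Kdm6a, Ddx3x and Eif2s3x to exceed every other library. That held for 2 of the 3. Eif2s3x did not, at 1.03 times the mean of the others, so the prediction failed as written. Its bound had made no allowance for the spread of that gene, which was 1.43-fold over the other 5 libraries, more than the rises of Kdm6a (1.38) and Ddx3x (1.26). A female embryo would not have the single Arx allele that the label wt/0 describes, so the genotype label of this library is in doubt. It is among the 3 libraries labelled wt/0 in the main comparison.

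The libraries with the group word first in their titles (replicate 3 of each group) stood apart from the other 4. Title style alone called 14 genes, among them Snord32a, Rps7, Rpl9 and Stmn1, and at most 1 gene was called in the other 14 ways to pick a pair of libraries. With the group as a further term it called 0, and 11 at an adjusted p under 0.10. A separate preparation or sequencing round could account for this: the share of low values at whole read lengths differed by -4.31 percentage points, outside the range of the other 4. More thalamic tissue is a further candidate, since both thalamus scores exceeded the highest of the other 4 by at least 0.33. None of the 14 genes called by title style is in the thalamus list, so that list gives no account of those calls. Thalamic tissue was not tested against the share of low values either. The explanations were not tested against each other, and both stay open. The style is balanced over the groups, and with it as a term limma called 0 genes. Under that term camera no longer called the synapse list (adjusted p = 0.0798) and called the thalamus list (adjusted p = 0.0307), both at the preset correlation.

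With 3 against 3 there are 10 splits, too few for a share under 0.05. For genes changed, 10 of 10 splits gave at least the real count, an outcome that a real count of 0 fixes in advance, so it tests nothing. The highest other split called 15 genes. It set wt/0 replicate 1 and dup24/0 replicates 1 and 2 against the rest, which puts both libraries of the word-first title style on one side, and what separates its sides was not tested. For called lists, 6 of 10 splits gave at least the real 9, and the highest other split called 15.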
